A study of Mus musculus with 7 samples.

How the data were processed

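The series holds 7 soleus muscle samples of wild-type cage-control mice. Soleus is a hindlimb muscle with many slow, oxidative fibres. The 7 titles carry different numbers, and 6 of them the code C15 and that of replicate 5 the code C16, whose meaning is not given in the sources used here. Nothing else states that the samples came from separate animals, so differences between these samples may be partly technical. The p-values of score correlations rest on pairings of the samples. Those of the list tests rest on random gene lists, those of neighbouring spots on shuffled positions, and that of the first component on samples permuted within each gene. With 1 group there is no contrast between conditions. Per the labels' protocols, total RNA was extracted from cryosections of the muscle belly with an RNeasy kit. It was reverse transcribed with gene-specific primers and labelled with a radioactive nucleotide, so each array has 1 colour. Because the primers were gene-specific, a transcript was labelled only where its primer was in the pool, and the signal of a spot also depends on its primer and probe. Levels of different genes were therefore not ranked against each other. The image analysis, background treatment, filters and software are not given in the sources used here.

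The authors deposited 1 value per spot and sample as a linear ratio, with 223 spots on each array. The sum of a column without spot 1M, which has no gene name here, and without the 28S ribosomal RNA spot lay between 0.9986 and 1.0002 in every sample. The deposited ratio was therefore taken as a spot's signal relative to the summed signal of the other spots, and is given below as a percent of that sum. The 28S spot and spot 1M are given on the same scale although they are not part of the sum. Most values have 4 decimals, so a value near the floor has 1 or 2 significant digits. In replicate 1, the values of Rps29 and Car3 have 6 decimals, for a reason not given in the sources used here. No value was at or under 0. All 7 value columns belong to samples of the series.

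Gene names came from the platform annotation of the array. Of the 223 spots, 205 had 1 gene symbol, 18 had none and 0 had several. The Entrez identifier of 204 of the 205 was found in the mouse RefSeq gene table of assembly GRCm38.p6, and none of these symbols changed. The remaining spot, annotated as POLB, carries a human identifier and kept that name. Igf1 and Fn1 had 2 spots each, which were averaged on the log2 scale, so that 203 genes were analysed. No coordinates are given because the array names no genome build.

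The following choices were made before the data were examined. Values as deposited were to be used if the median and total of every column lay within 10% of the mean over columns. Here the total ran over all 223 spots, with spot 1M and the 28S spot included. Quantile normalization between arrays was to be used otherwise. Only 1 of the 7 columns met that limit, so quantile normalization over the 223 spots was used, followed by log2 with no pseudocount. This gives every array the same set of values, so a gene that holds the same rank on all arrays has an SD of 0. Genes were grouped in 15 fixed lists, of which 13 had a gene on the array. For each of the 9 lists with at least 3 genes, the median SD and the mean pairwise Pearson r over the samples were set against 10000 random lists. These had the same size and were matched on mean level in 5 bins. The permutation p was two-sided and adjusted by Benjamini-Hochberg over the 9 lists. A list's score in a sample is the mean over its genes of the log2 signal minus the gene's mean. Scores of fixed pairs of lists were correlated with an exact permutation test over all 5040 pairings of the 7 samples, two-sided, adjusted over the pairs. Of the 10 planned pairs, 6 could be tested; the other 4 needed a list with under 2 genes on the array. The share of variance on the first principal component was set against 100 draws with the samples permuted within each gene. Genes were named by a fixed rule. It takes the first 3 measured genes of each list. It adds the 5 genes with the largest and the 5 with the smallest SD among those whose mean lies above the median over genes. This gave 42 genes. The lists for membrane channels and for nerve had 0 genes on the array.

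The files give no background reading, no counts and no detection call, so depth does not apply, and the number of arrays limits the precision. After seeing that most values lay near a lower limit, each array's 10th percentile was taken as its floor. A gene was called above the floor if every one of its spots exceeded 2 times that value on all 7 arrays, and near the floor otherwise. A value near the floor is not evidence that the transcript was absent. Also after seeing the data, gene levels were given as deposited (mean ± SD, n = 7), while spreads and correlations are on the quantile-normalized log2 scale. Genes named beyond the fixed rule are list members above the floor, or were chosen after their values were seen. The 18 spots without a gene symbol entered the normalization and no gene list.

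Alternatives planned before the data were examined were the values as deposited, equal array medians, equal array totals and a pseudocount of 0.04%. Equal totals used the sum over all 223 spots, with spot 1M and the 28S spot included. As a ratio, that sum ran from 1.50 in replicate 5 to 2.66 in replicate 1. Spot 1M ran from 36.98% to 153.41% in the same replicates, so this setting rescales the arrays mainly by spot 1M. A filter on genes under the 25th percentile of mean level and leaving out each replicate were planned too, as were Spearman's rho, a median score and the median absolute deviation. Added afterwards were the genes above the floor alone and the same genes with the floor subtracted from the deposited values, without quantile normalization. So was removal of a quadratic trend in spot position, fitted to the near-floor spots of each array. Spot positions were read from the spot IDs, each a number and a letter, taken as grid coordinates.

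The list and pair tests were tested on simulated data over the 203 genes in 20 simulations. A list given 2 times the SD was called in 20 of 20, with 3 calls among 100 unchanged lists. A list given a shared factor of 1 residual SD was called as varying together in 20 of 20, with 1 call among 100 unchanged lists. A pair of lists sharing such a factor was called in 14 of 20, with 1 call among 100 pairs that shared none. Apart from the added effects, the simulated noise was independent between genes, with the same SD for all. It had no trend in spot position, no floor and no normalization step. These rates may therefore not hold for the arrays themselves. The larger SD was given to the fatty acid list of 11 genes and the shared factor to the vessel list of 20. The pair was the matrix and myogenic lists, of 18 and 17 genes. Detection of an effect in lists of 2 or 3 genes was not simulated. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.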

Results

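Soleus muscle of wild-type cage-control mice was measured in 7 samples, 1 array each, with 205 named spots for 203 genes. Each value is a spot's signal as a percent of the summed signal of its array without spot 1M and the 28S ribosomal RNA spot. The 28S spot lies outside that sum but is counted among the 203 genes. All 203 genes had a value above 0 in all 7 samples. Of these, 44 genes lay above the floor on all arrays and 159 lay near it. The floor ranged from 0.02% in replicate 5 to 0.13% in replicate 1, and the column medians from 0.06% to 0.20%. The series describes 1 condition, so the questions are how large each transcript's signal was, how much it varied between samples, and which gene groups varied together.

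The contractile genes on the array were all above the floor. Myh7, the slow myosin heavy chain, stood at 8.91% ± 2.09 (SD, n = 7), the only one of the 12 listed slow fibre genes on the array. Myh2 and Myh1, the fast heavy chains IIa and IIx, stood at 2.52% ± 0.535 and 2.41% ± 0.497. Myh4, the fast heavy chain IIb, was at 0.890% ± 0.114. Myoglobin (Mb), which binds oxygen in muscle, was at 8.10% ± 0.991, with a coefficient of variation of 12.2%. Desmin (Des), an intermediate filament protein of muscle, was at 2.10% ± 0.605. Levels of different genes depend on their primers and probes, so these values do not rank the transcripts.

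Genes of energy metabolism were mostly above the floor. Of the 11 fatty acid genes on the array, 8 lay above it. Among them were Fabp3, the muscle fatty acid binding protein, at 0.449% ± 0.106 (SD, n = 7), Cd36, a fatty acid transporter, at 0.890% ± 0.275, and Lpl, lipoprotein lipase, at 0.727% ± 0.166. Hadh, an enzyme of beta-oxidation, was at 0.674% ± 0.0907. Of the 6 genes of the citrate cycle and respiratory chain, 5 lay above the floor. Mdh2, mitochondrial malate dehydrogenase, was at 0.551% ± 0.103. The cytochrome oxidase subunits Cox4i1, Cox5b and Cox6a2 were at 2.07% ± 0.266, 2.45% ± 0.527 and 7.21% ± 2.40. Tfam, the mitochondrial transcription factor, lay near the floor. Of the 10 glucose genes, 6 lay above it. They included the insulin-responsive transporter Slc2a4 at 0.516% ± 0.0909 and the glycolytic enzymes Aldoa at 10.8% ± 2.65, Gapdh at 10.4% ± 2.27 and Pgk1 at 0.416% ± 0.0387. The transporters Slc2a1 and Slc2a3 lay near the floor, both with a mean of 0.123%.

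**Figure D1:**
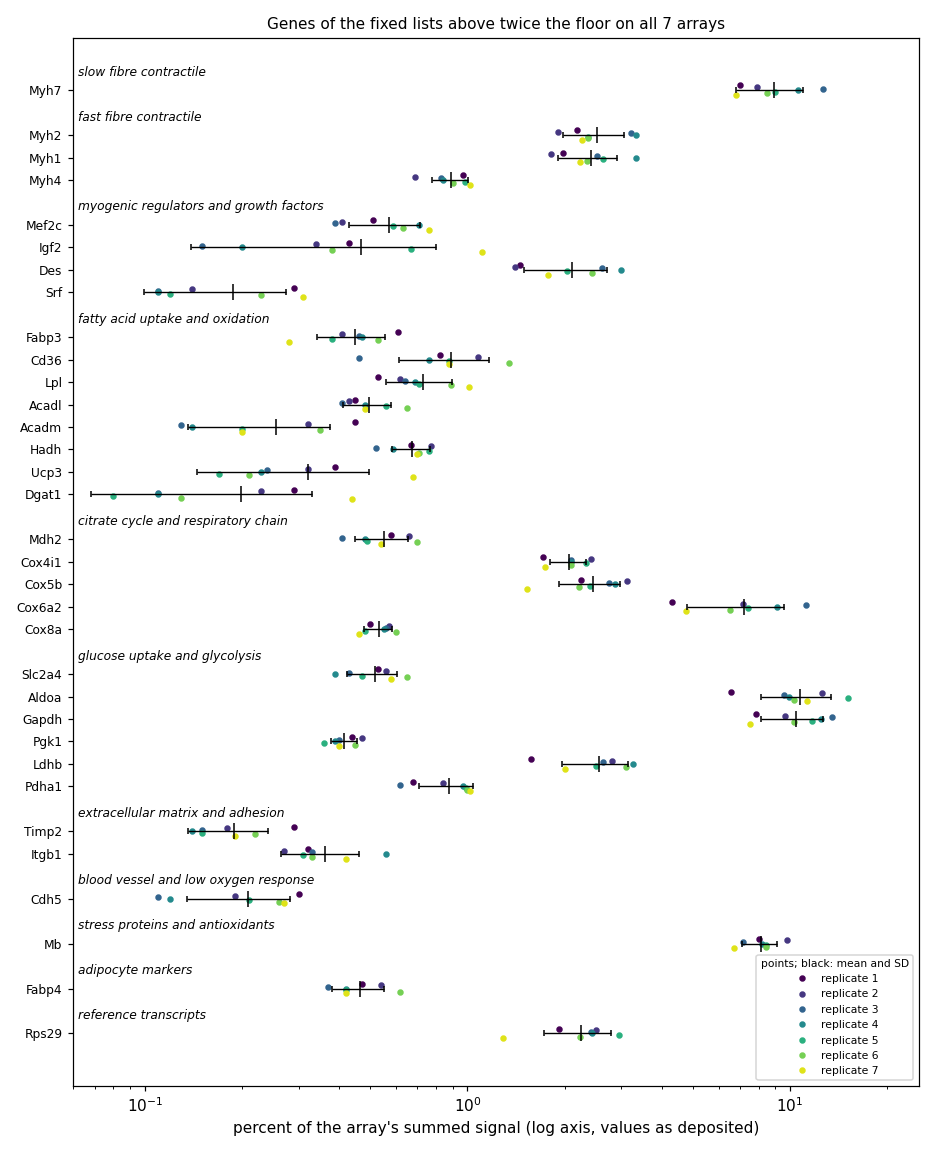
Deposited signal of the genes of the fixed lists that lay above 2 times the floor on all 7 arrays, grouped by list, as a percent of the summed signal of the array on a log axis. Each point is 1 replicate and the black bar the mean and SD; Myh7 averaged 8.91%, Mb 8.10% and Srf 0.187%.

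Regulators of muscle formation lay mostly near the floor, with 4 of 17 genes above it. Mef2c, a muscle transcription factor, was at 0.571% ± 0.142 (SD, n = 7) and Igf2, insulin-like growth factor 2, at 0.469% ± 0.330. The muscle determination factors Myod1, Myog and Myf5 lay near the floor, at 0.101% ± 0.0946, 0.0843% ± 0.0716 and 0.0714% ± 0.0524. In the matrix list, 2 of 18 genes lay above the floor, the protease inhibitor Timp2 at 0.189% ± 0.0527 and the integrin Itgb1 at 0.363% ± 0.0979. Tenascin C (Tnc), Fn1 and Lama2 lay near it. In the vessel list, 1 of 20 lay above it, the endothelial cadherin Cdh5 at 0.209% ± 0.0738. Vegfa, a growth factor of blood vessels, and Vegfc lay near it. Vegfb, with a mean of 0.217%, exceeded 2 times the floor on 6 of the 7 arrays and so is counted as near it. The 2 immune genes, Il1b and Il6, lay near the floor, as did the 3 genes of protein breakdown, Ctsh, Capn3 and Cast. Of the adipocyte markers, Fabp4 was at 0.466% ± 0.0864 and Pparg lay near the floor. Of the reference transcripts, the ribosomal protein gene Rps29 was at 2.25% ± 0.527, and Hprt and Ywhaz lay near the floor. With these levels near the floor, differences between samples in most regulators, matrix and vessel genes cannot be separated from variation of the floor.

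The median SD between samples was 0.25 on the log2 scale over all 203 genes, and 0.68 in the deposited values. As deposited, the median coefficient of variation was 23.4% for genes above the floor and 53.2% for those near it. On the quantile-normalized scale that gap was not seen, with a median SD of 0.26 above the floor and 0.23 near it. Among genes above the median level, Il6st, the shared receptor subunit of the interleukin 6 family, had the largest SD, 1.03, with deposited values from 0.21% to 1.89%. It was followed by the cyclin Ccna1 at 0.76, Igf2 and the vessel ligand Angpt2 at 0.70 each, and angiogenin (Ang) at 0.66. Of these 5, Il6st and Igf2 lay above the floor on all arrays, Ccna1 and Angpt2 on 5 and Ang on 2. The smallest SDs were those of the carbonic anhydrase Car3 at 0, Lamb2 at 0.08, Cox4i1 at 0.12, Ldhc at 0.13 and Timp1 at 0.14. Car3 held the same rank on all arrays, and its deposited values averaged 1.38% ± 0.260 (SD, n = 7). In the deposited values the SDs of Lamb2, Ldhc and Timp1 were 0.53, 0.69 and 0.56, so their small spread belongs to the quantile scale.

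No gene list differed in spread from random lists of the same size and level, with 0 of 9 past the adjusted threshold and 1 at an unadjusted permutation p under 0.05. That list held the glucose genes, whose median SD was 0.22 against 0.29 in random lists (permutation p = 0.0448, adjusted p = 0.333). The fatty acid genes had a median SD of 0.35 against 0.29 (adjusted permutation p = 0.333). The fast fibre genes had 0.21 against 0.31 (adjusted permutation p = 0.333). With the trend in spot position removed, the fatty acid list passed with a lower spread than random lists, 0.18 against 0.28 (adjusted permutation p = 0.0036). In the deposited values the matrix list passed with a lower spread, 0.60 against 0.71 (adjusted permutation p = 0.0234). On the quantile-normalized scale the fatty acid list lay above random lists and the matrix list, at 0.26, was level with them.

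Members of a list were not high or low together beyond random lists in any of the 9 lists, with 0 past the adjusted threshold and 0 at an unadjusted permutation p under 0.05. The mean r lay above the median of random lists in 8 lists and below it for the reference transcripts. The vessel list had a mean pairwise r of 0.0876 (permutation p = 0.0672, adjusted p = 0.605), which was -0.00610 without replicate 1 and -0.0333 with the position trend removed. The fast fibre list, Myh2, Myh1 and Myh4, had a mean r of 0.327 (adjusted permutation p = 0.747). It was 0.0778 without replicate 2, 0.776 with the position trend removed and 0.968 with equal medians, and did not pass in any of these (adjusted permutation p = 0.990, 0.0756 and 0.134). The spots of Myh2, Myh1 and Myh4 share the letter O, at numbers 16, 18 and 20, so a fitted trend takes similar amounts from each. Equal medians also shift all genes of an array alike. Either step can raise r by itself.

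The fatty acid and glucose scores varied together over the 7 samples, the only one of 6 pairs of lists to pass. Pearson's r was 0.920 (95% interval 0.545 to 0.988; exact permutation p = 0.00357, adjusted p = 0.0214). Spearman's rho was 0.857 (exact permutation p = 0.0238, adjusted p = 0.143), and r was 0.761 without replicates 2 and 7, the farthest from the median fatty acid score. Among the 8 fatty acid and 6 glucose genes above the floor, r was 0.351 (exact permutation p = 0.440), and it was 0.765 without replicate 1 and 0.00604 without replicate 7. The adjusted exact p was 0.0667 without replicate 3, 0.0750 without replicate 5 and 0.317 without replicate 7, and the call was also lost with the position trend removed (r = 0.771, adjusted exact p = 0.212).

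The other pairs did not pass. Fatty acid and respiratory scores gave r = 0.713 (exact permutation p = 0.0718, adjusted p = 0.215; rho = 0.571, p = 0.2), and 0.406 without replicates 2 and 7. Matrix and myogenic scores gave r = -0.483 (exact permutation p = 0.279, adjusted p = 0.418; rho = -0.750, p = 0.0663), and -0.914 without replicates 3 and 4. Immune and matrix scores gave r = -0.505 (exact permutation p = 0.263, adjusted p = 0.418; rho = -0.429, p = 0.354), and -0.105 without replicates 1 and 7. Fast fibre and glucose scores gave r = -0.163 (exact permutation p = 0.740, adjusted p = 0.888; rho = 0.0357, p = 0.963), and 0.313 without replicates 2 and 3. Vessel and respiratory scores gave r = 0.0198 (exact permutation p = 0.965, adjusted p = 0.965; rho = 0.107, p = 0.840), and 0.0528 without replicates 1 and 5. Fatty acid and respiratory scores passed without replicate 6 (r = 0.917, adjusted exact p = 0.0375), and matrix and myogenic scores without replicate 4 (r = -0.883, adjusted exact p = 0.0417). Scaling changed signs: matrix and myogenic scores gave r = 0.966 and immune and matrix scores 0.991 in the deposited values, and fast fibre and glucose scores 0.929 with equal medians.

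**Figure D2:**
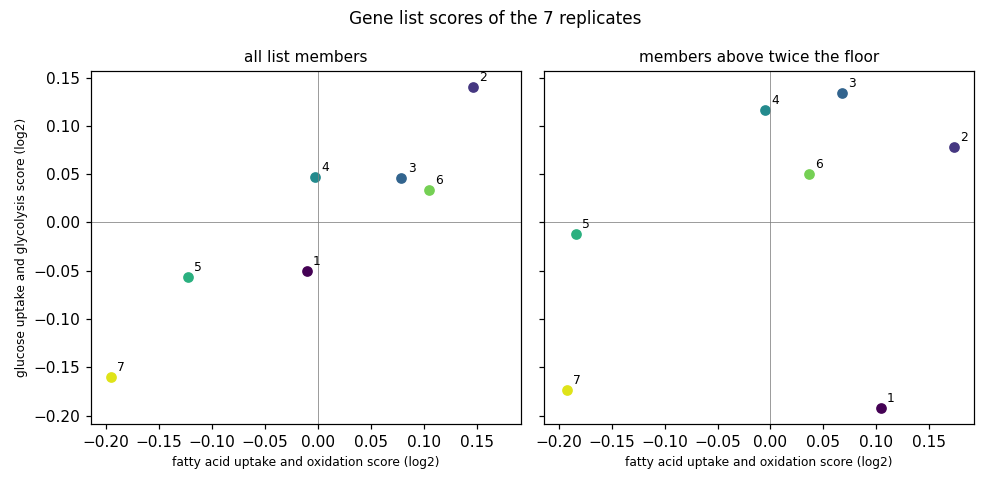
Glucose score against fatty acid score on the quantile-normalized log2 scale, with each point 1 replicate, over all list members (left) and over members above 2 times the floor (right). Replicate 7 is lowest and replicate 2 highest on both axes at left (r = 0.920), while at right replicate 1 is lowest in glucose score and r is 0.351.

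The first axes held more of the variance than in permuted data. The first principal component took 42.6% against a median of 23.1% and a highest value of 27.3% over 100 permuted draws (permutation p = 0.0099, the smallest these draws can give). The second took 33.8%, also above that highest value, but was not itself tested. On the first, replicate 7 lay at one end with a score of 0.763, and replicates 3 and 4 at the other with -0.469 and -0.405. Over all genes, mean r of each sample with the others ranged from 0.940 in replicate 7 to 0.973 in replicate 6. Replicates 3 and 4 were the closest pair at r = 0.994, with 42 identical deposited values. Replicates 2 and 6 shared more, 64, at r = 0.986, and all 7 were kept as separate samples.

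Near-floor spots next to each other on the array deviated together, in 1 direction of the grid in all 7 replicates and in the other in 6. Between spots of successive numbers, r over 119 spot pairs was 0.728 in replicate 1 and 0.514 in replicate 7 (permutation p = 0.0001 for each, the smallest that the shuffles can give). It ranged from 0.247 to 0.370 in the other replicates. Between spots of successive letters, r over 123 spot pairs was 0.537 in replicate 1, 0.366 in replicate 7 and from 0.104 to 0.328 in the others. There replicate 5 did not pass (r = 0.104, adjusted permutation p = 0.106). In replicate 1, 17 of 19 near-floor spots with the letter B were above their mean over samples, among them Myod1 and Il1b. In replicate 7, the same held for 19 of 19 near-floor spots of numbers 3 to 7 and letters H to O, among them Tnc. These spot pairs are not independent replicates, and the blocks were chosen after their values were seen. A spot's deviations are taken from its mean over the same 7 arrays. Strong patterns in replicates 1 and 7 therefore return in part, with opposite sign, in the other replicates. The r of those replicates is thus not separate evidence of an effect of position on each array.

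**Figure D3:**
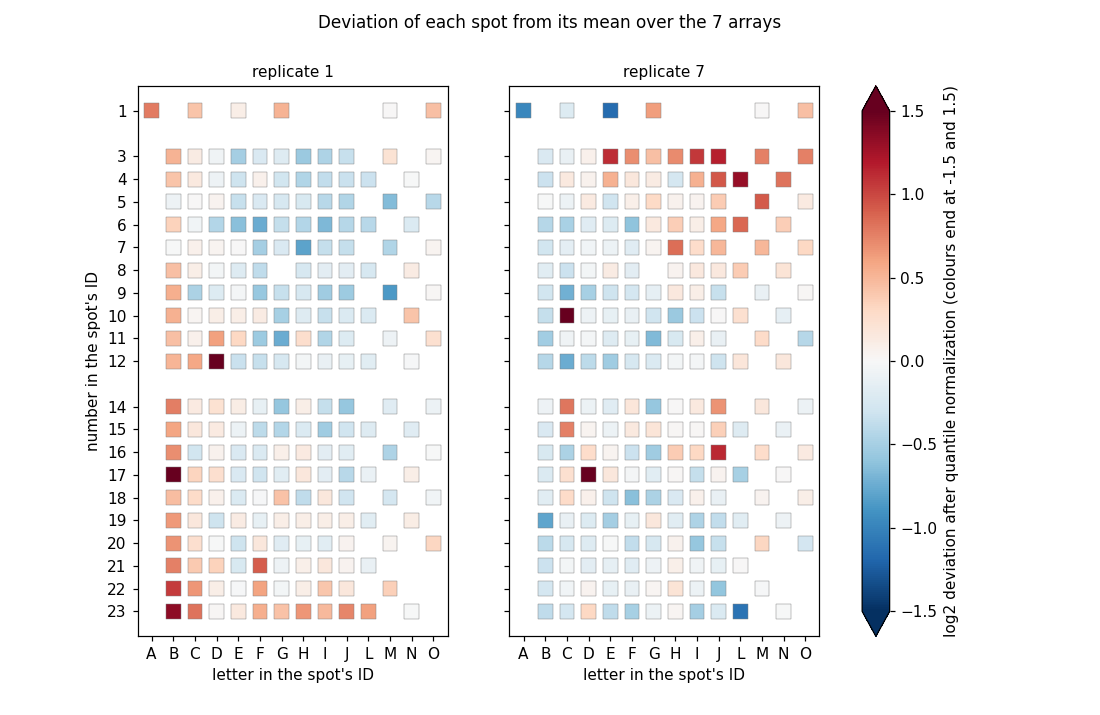
Deviation of each spot from its mean over the 7 arrays in replicate 1 (left) and replicate 7 (right), in log2 units after quantile normalization, drawn at the number and letter of its spot ID, with red above and blue below the mean. Near-floor spots with the letter B are high in replicate 1 (median 0.54), and those of numbers 3 to 7 and letters H to O in replicate 7 (median 0.53).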

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

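The technical tests given here were chosen after the results were seen, and with 1 group no biological explanation was tested.

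Of 57 values examined, 42 of them named genes, 7 had 1 sample far from the other 6, and all 7 were named genes. About 1 in 20 would do so among independent normal values. That rate need not hold here, since 6 of the 7 genes lay near the floor, where values have few digits. The gap to the nearest sample, as a share of the whole range on the quantile-normalized log2 scale, was 0.850 for Myod1, 0.832 for Myog, 0.659 for Myf5 and 0.934 for Il1b, all high in replicate 1. It was 0.602 for Slc2a1, high in replicate 2, 0.649 for Tnc, high in replicate 7, and 0.639 for Rps29, low in replicate 7. In deposited values, Myod1 was at 0.31% against 0.04% to 0.10%, Il1b at 0.31% against 0.02% to 0.09%, and Tnc at 0.45% against 0.06% to 0.21%. Slc2a1, at 0.15%, lay inside the deposited range of the others, 0.06% to 0.21%.

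For the 6 of these genes near the floor, position on the array is a candidate explanation. The median of the neighbouring near-floor spots, other outlying genes left out, deviated the same way in 6 of 6, by a median of 0.50 log2 units. Tnc had 1 such neighbour, Myod1 and Slc2a1 had 2 each, Myog 3, Il1b 5 and Myf5 8. For Il1b, 4 of the 5 went its way, and for the other genes all did. The 6 genes are not independent cases. Myod1, Myog, Myf5 and Il1b stood apart on the same array, and Myod1 and Myog shared the spots of Mmp12 and Mmp8 as neighbours. Related genes placed side by side are another candidate. In replicates 1 and 7, spots of successive numbers gave r = 0.728 and 0.514, against 0.537 and 0.366 for successive letters. These differences were not tested. Some related genes also have successive numbers, such as Mmp14 and Mmp12 with the letter B, so r along the numbers cannot exclude this explanation. In replicate 2, where Slc2a1 stood apart, the order was opposite, 0.247 against 0.328. The explanation by related genes stays open in all these replicates. In all 6 the neighbours deviated less than the gene itself, by 0.34 against 1.68 for Il1b, 0.17 against 0.41 for Myf5 and 0.86 against 1.34 for Myod1. The genes were picked for an extreme value and their neighbours were not, so this comparison cannot tell how much of these values position accounts for. The low value of Rps29, above the floor and with 0 near-floor neighbours, was not covered by these tests.

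For the fatty acid and glucose scores, none of the 3 technical explanations could be excluded. One replicate alone stays open, since the lowest r with 1 replicate left out was 0.829, without replicate 7, where the adjusted exact p was 0.317. Signal near the floor stays open. Members above the floor gave r = 0.351 (95% interval -0.547 to 0.873). The same members gave 0.0214 with the floor subtracted from deposited values. That setting also leaves out the quantile normalization, so the change cannot be assigned to the floor alone. Near-floor members of both lists gave -0.0974. Members above the floor of 1 list against near-floor members of the other gave 0.836 and 0.813. Position stays open too, since r was 0.771 with its trend removed, no longer past the threshold and not near 0. With 7 samples these cannot be told apart.

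The 5 genes with the largest SD, Il6st, Ccna1, Igf2, Angpt2 and Ang, of which Ccna1, Angpt2 and Ang lay near the floor, varied together, with a mean pairwise r of 0.854. A quadratic trend in position is argued against as the whole cause, since the mean r was 0.896 with it removed. The central 95% of random lists ended at 0.560. A signal that follows 28S ribosomal RNA stays open, with r = 0.753 between the mean of the 5 genes and 28S in deposited log2 values (exact permutation p = 0.0583; rho = 0.536, p = 0.236), and -0.460 without the 2 farthest samples. On the quantile-normalized scale r was 0.698 (exact permutation p = 0.0952; rho = 0.598, p = 0.171). The 5 genes were picked for their spread, and the random lists were not matched on spread.

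Spots without a gene name also carried signal. Spot 1C averaged 2.46% ± 0.763 (SD, n = 7), and spot 1M averaged 99.4% ± 38.2, from 36.98% in replicate 5 to 153.41% in replicate 1. Spot 10C, which did not exceed 2 times the floor on every array and so counts as near it, averaged 0.523% ± 0.506, from 0.07% to 1.49%. On the quantile-normalized scale its signal followed the mean of the 5 genes above, with r = 0.987 (exact permutation p = 0.000397, adjusted p = 0.00675) and rho = 0.964 (p = 0.00278, adjusted p = 0.0472). It was the only one of 17 unnamed spots to pass, a family tested after the result was seen, and r was 0.981 without replicates 5 and 7.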

How the results depend on the processing

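The 3 settings using the floor or spot position were chosen after seeing the data, and the others were planned. With the floor subtracted, the values were the deposited ones without quantile normalization. Changes in that setting therefore mix floor subtraction with the lack of normalization. Equal totals include spot 1M and the 28S spot. Results with equal totals therefore show dependence mainly on spot 1M, not on the summed signal of the other spots, which was already level between arrays. The first component took from 44.4% without replicate 3 to 82.1% as deposited; its permutation p was 0.0099 in each setting, the smallest that 100 draws can give, so it does not measure stability. No list varied together in the settings run. The median SD was 0.68 as deposited, 0.36 with equal medians, 0.56 with equal totals, 0.19 with the pseudocount, 0.27 without low values, 0.26 above the floor, 0.39 with the floor subtracted and 0.21 with the position trend removed. It was 0.23 to 0.25 with 1 replicate left out. Restriction to genes above the floor left 44 genes. Lists past the spread threshold numbered 1 as deposited and 1 with the position trend removed. The first was the matrix list (0.596), below random lists there and level with them on the quantile-normalized scale. The second was the fatty acid list (0.184, reversed). Pairs of lists past the threshold numbered 3 as deposited, 4 with equal medians, 3 with equal totals, and 0 with the pseudocount, above the floor, with the floor subtracted, with the position trend removed, by rho and by the median score. With 1 replicate left out they numbered 0 to 2. Fatty acid and glucose scores lost their call with the pseudocount (r = 0.883), above the floor (0.351), with the floor subtracted (0.0214), with the position trend removed (0.771), by rho (0.857) and by the median score (0.768), with adjusted exact p from 0.00476 to 0.954 over all alternatives. Leaving out 1 replicate gave 0.829 to 0.95. Fatty acid and respiratory scores gave 0.947 with equal medians, -0.384 with the floor subtracted, and 0.475 to 0.917 with 1 replicate left out. Fast fibre and glucose scores turned sign with equal medians (0.929), equal totals (0.367), above the floor (0.0694), with the floor subtracted (0.248), with the position trend removed (0.120) and by rho (0.0357), and ranged from -0.336 to 0.456 with 1 replicate left out. Vessel and respiratory scores gave -0.0754 as deposited, 0.810 with equal medians, -0.498 with equal totals, -0.0586 with the pseudocount, -0.0424 without low values, -0.168 by the median score and -0.247 to 0.126 with 1 replicate left out. Matrix and myogenic scores gave 0.966 as deposited, 0.509 with equal medians, 0.929 with equal totals, 0.376 with the floor subtracted and -0.883 to -0.245 with 1 replicate left out. Immune and matrix scores gave 0.991 as deposited and 0.971 with equal totals. Mean r with the other samples, for replicate 1, was 0.966 above the floor, 0.956 with the floor subtracted and 0.966 with the position trend removed. With the floor subtracted it was 0.957 for replicate 2, 0.940 for 3, 0.944 for 4, 0.957 for 6 and 0.906 for 7, and replicate 7 had 0.955 with the position trend removed. Of the 42 named genes, the SD of 40 moved as deposited, 40 with equal totals, 31 with the position trend removed, 28 with equal medians and 20 with the pseudocount, and 15 of 17 with the floor subtracted, by more than the SD of its values with 1 replicate left out. Apart from the smaller number of genes or samples in some settings, the cause was not tested. No paired analysis was possible because the series has 1 group. Signal over background limits the 159 genes near the floor.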

Other observations

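Outside the gene lists, 11 genes lay above the floor, named after their values were seen. Titin (Ttn), the giant spring protein of the sarcomere, was at 2.46% ± 0.481 (SD, n = 7). Car3, a carbonic anhydrase abundant in slow muscle, was at 1.38% ± 0.260. Igfbp6, which binds insulin-like growth factors, was at 0.609% ± 0.241, and Vldlr, a lipoprotein receptor, at 0.230% ± 0.0455. The glycolytic isoenzymes Aldoc and Eno2, best known from nervous tissue, were at 0.354% ± 0.102 and 0.293% ± 0.0883. The glucose transporter Slc2a2, best known from liver, was at 0.239% ± 0.0467. Cross-hybridisation between related transcripts was not tested.

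The 28S ribosomal RNA spot averaged 12.0% ± 5.93 (SD, n = 7), from 3.88% in replicate 3 to 21.62% in replicate 2.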
